A study of Mus musculus with 8 samples.

How the data were processed

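Total RNA of sorted LLC and colon26 tumour cells was extracted with Trizol, and biotin-labelled cRNA made from 6 ug of it was hybridised to 1-colour Affymetrix mouse arrays, per the labels. The authors summarised the 45101 probe sets of each of the 8 arrays by RMA, per the submitters' processing notes, and the deposited values are on a log2 scale. The RMA software, its version and options, and which arrays were normalized together are not given in the sources used here. The arrays' value distributions were not identical, so quantile normalization and median centring were tried as alternatives. The descriptions of the 4 colon26 samples name LLC, whereas their titles, source and cell line fields say colon26, and the latter were followed. The number of arrays, 2 in each of the 4 groups, limits the precision.

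Probe sets were joined to genes by the platform's annotation: 34945 carried 1 gene symbol, 932 several, 9160 none, and 64 were controls. Symbols were matched to RefSeq genes of the mouse assembly GRCm38.p6, used for names only; no genome coordinates enter the results. Each gene was represented by its probe set with the highest mean over the 8 arrays, and the 12177 genes with a log2 value above 5 in at least 2 arrays were tested; probe sets with several or no gene symbols and controls were left out.

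Models were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment within a contrast at 0.05. The contrasts were EGFP-high minus EGFP-low in LLC, in colon26 and as the mean of the lines, and the LLC change minus the colon26 change. The first model had 4 group means (4 residual degrees of freedom, prior 2.34). An alternative set in advance added the replicate number within each line as a block (2 residual degrees of freedom, prior 8.25). Low and high arrays of the same number shared their deviations from the group means, so values with the block are given throughout, with those without it beside the counts. In simulated data 200 of 12177 genes were changed (20 simulations). The blocked model recovered 61.3% of log2 changes of 1 in LLC, 60.5% in colon26 and 95.6% over both lines, and the share of false calls was 4.4%, 4.7% and 5.0%. Without the block 0% of log2 changes of 1 or 2 were recovered in either line, and 0.4% and 51.7% over both lines. The simulation used the real shifts between the numbers and independent noise drawn from the blocked fit's own prior. The blocked model was thus true by construction, and its share of false calls is not tested for the real genes, which move together. The overlap of calls used Fisher's exact test.

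Gene lists, 14 for cell programmes and 10 for other cell types, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, and Benjamini-Hochberg adjustment over the lists of a contrast; lists with fewer than 3 genes tested were left out of this step. The groups, contrasts, filter, tests, alternatives, gene lists and the rule for genes to name were fixed before the data were examined. That rule took the 10 genes with the largest rise and the 10 with the largest fall among those passing the adjusted p and with both high arrays on the same side of both low arrays, 5 of each sign for the difference between lines, Gins1 in every contrast, and up to 4 passing members of each list by smallest p, or the 2 with the highest mean where none passed. If no gene passed, the 5 with the smallest p were given as values. Its use on the blocked model as well as on the first was decided after the pairing was seen. Pou5f1, Nanog, Sox2, Xist, Eif2s3y and the members of gene families were named after their values were seen.

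Alternatives were no filter, a filter of 7, only the arrays of a line, quantile normalization, median centring, mean-variance trend with robust moderation, array weights, the mean of all probe sets of a gene, every probe set as its own unit, and leaving out each array; the filters, the arrays of a line, the scalings, the moderation and the probe set choices were repeated with the block. These repeats, leaving out each pair, and a block shared by the lines were chosen after the data were seen; array weights were not combined with the block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.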

Results

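Expression was measured in tumour cells sorted by the activity of the promoter of PSF1, the protein encoded by Gins1, which is a subunit of the GINS complex that works with the MCM helicase at replication forks. The cells came from 2 mouse tumour lines, Lewis lung carcinoma (LLC) and the colon carcinoma colon26, each carrying EGFP under the mouse PSF1 promoter. Tumours grew under the skin for 4 weeks (LLC) or 2 weeks (colon26), were dissociated, and were sorted by FACS into cells with low and with high EGFP. Each of the 4 groups had 2 arrays, numbered 1 and 2 and called biological replicates in the labels. The labels do not say whether these came from separate tumours or mice, so the p-values describe the spread among these arrays only. Without the block that is the spread between the 2 arrays of a group. With it, the spread is that of the high minus low difference between the numbers of a line, pooled over the lines. The median log2 signal of the 45101 probe sets was 4.85 and 4.79 in LLC low, 4.86 and 4.76 in LLC high, 4.98 and 5.02 in colon26 low, and 4.97 and 4.87 in colon26 high. Between 10565 and 11869 of the 18193 named genes lay above a log2 signal of 5 on each array, and the number of arrays limits the precision of every value.

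The arrays numbered 1 and 2 differed in RNA representation in all 4 groups. The median log2 difference between the 3′ and 5′ probe sets of 4 control transcripts (Actb, Gapdh, Pcx and Tfrc) was 2.55 ± 0.13 (SD, n = 4) on the arrays numbered 1 and 0.18 ± 0.15 (SD, n = 4) on those numbered 2. High minus low of this difference was 0.22 and −0.15 in the LLC pairs and −0.18 and 0.11 in the colon26 pairs. The median absolute difference per gene between single arrays was 0.44 between the 2 numbers of a group and 0.24 between the high and low arrays of a line and number. Across genes, which are not independent replicates, each of the 8 arrays correlated most closely with the array of the other sort that had its own line and number. Pearson r was 0.974 and 0.962 for the LLC pairs and 0.978 and 0.961 for the colon26 pairs. Low and high arrays of the same line and number were therefore treated as pairs. A gene is said to have risen or fallen where its adjusted p was under 0.05 in limma with the pair as a block. Changes are EGFP-high minus EGFP-low on the log2 scale, and each gene's value is that of 1 probe set, the one with the highest mean.

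**Figure D1:**
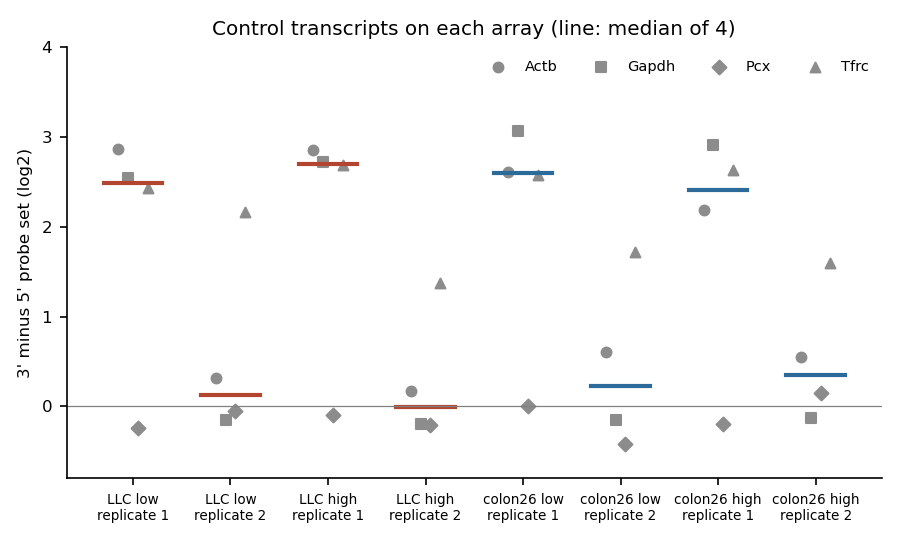
Log2 signal of the 3′ minus the 5′ probe sets of 4 control transcripts on each of the 8 arrays, with a line at the median of the 4. The medians are 2.41 to 2.70 on the arrays numbered 1 and −0.01 to 0.35 on the arrays numbered 2, while Pcx alone lies close to 0 on both.

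Gins1 itself followed the sort in both lines. In LLC its log2 signal was 7.19 ± 0.06 (SD, n = 2) in low and 8.47 ± 0.06 (SD, n = 2) in high cells (Entrez gene 69270), a rise of 1.28 (SE 0.21, limma adjusted p = 0.0033) or 2.43-fold. In colon26 it was 7.27 ± 0.42 (SD, n = 2) in low and 8.33 ± 0.06 (SD, n = 2) in high cells, a rise of 1.07 (SE 0.21, limma adjusted p = 0.017) or 2.09-fold. The difference between the lines was 0.21 (limma adjusted p = 0.78). Over both lines the other subunits Gins2, Gins3 and Gins4 rose by 0.65, 0.72 and 0.54. Without the block the adjusted p of Gins1 was 0.23 in LLC and 0.64 in colon26. With it, the LLC call ended without the LLC pair numbered 2 (change 1.19, adjusted p = 0.052), and the colon26 call ended without the colon26 pair numbered 1 (1.41, 0.053) or 2 (0.73, 0.35) and after quantile normalization (0.90, 0.080).

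**Figure D2:**
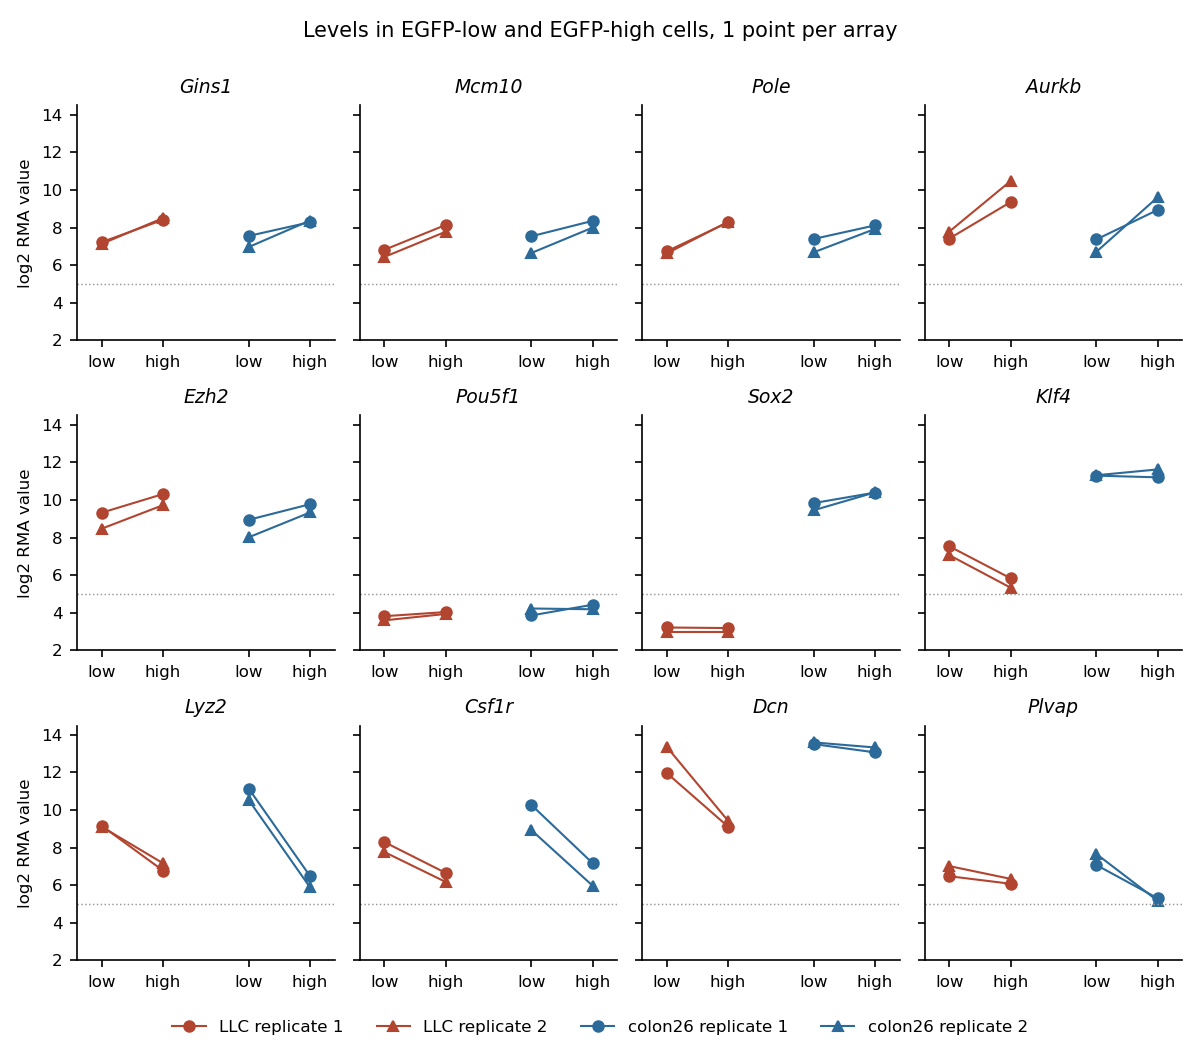
Log2 signal of 12 genes on each array, with lines joining the low and high arrays of the same line and number and a dotted line at 5. Gins1, Mcm10, Pole and Aurkb lie higher in all 4 high arrays than in their low partners, Pou5f1 stays under 4.5 on every array, and Lyz2 and Csf1r lie lower in all 4 high arrays.

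The LLC comparison asked what set EGFP-high apart from EGFP-low cells of the lung carcinoma. Genes of DNA replication and mitosis rose in high cells, and most of the fibroblast and macrophage markers tested fell. Aurkb, a mitotic kinase of the chromosomal passenger complex, went from 7.60 ± 0.26 to 9.92 ± 0.79 (SD, n = 2 each), and Depdc1b from 5.79 ± 0.00 to 8.35 ± 0.05 (SD, n = 2 each). Dcn, a small matrix proteoglycan made by fibroblasts, went from 12.67 ± 0.99 to 9.27 ± 0.22 (SD, n = 2 each), and Lyz2, a lysozyme of myeloid cells, from 9.14 ± 0.04 to 6.98 ± 0.27 (SD, n = 2 each). The limma adjusted p-values were 0.0010 for Aurkb, 1.5e-04 for Depdc1b, 8.9e-05 for Dcn and 1.7e-04 for Lyz2. Of 12177 genes tested, 607 rose and 735 fell, of which 284 and 379 by more than 2-fold. After quantile normalization 640 rose and 540 fell, and after median centring 662 and 791, so which direction had more calls depended on the scaling. The rises largest in size after Depdc1b (2.56) were those of Nusap1 and Aurkb (2.32 each), Aurka (2.31), Ccnf (2.28), Spag5, Fam83d and Ube2c (2.27 each), Pimreg (2.25) and Depdc1a (2.23). The falls largest in size were those of Aspn (−4.70), Mmp12 (−3.79), Postn (−3.48), Col1a2 (−3.40), Dcn (−3.39), Dpt (−3.36), C1s1 (−3.26), Bmf (−3.23), Osr2 (−3.17) and Lum (−2.97). Aspn, Mmp12, Postn, Bmf and Osr2 had means under 5 in LLC high cells, where background limits a fall, so the size and rank of these falls are not exact. Without the block, limma called 0 genes, with 794 at an unadjusted p under 0.05 against 609 from chance. The smallest p-values were then those of Arg1 (−2.83), Ddr1 (−2.79), Vcan (−2.90), Fn1 (−2.81) and Bmf, at adjusted p from 0.12 to 0.13. With the block, 716 genes were called without the LLC pair numbered 1 and 396 without the pair numbered 2.

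In the LLC gene lists, 30 of 30 G2 and mitosis genes rose (30 adjusted over the list alone; median change 1.89), among them Ndc80 (1.91) and Cenpe (2.17) of the kinetochore. Others were Cdk1 (2.02), the kinase of mitotic entry, and the spindle motor Kif11 (2.17). Of 29 S phase genes 21 rose (27 adjusted over the list alone; median 0.99), including the replicative polymerase subunits Pole (1.61) and Pold2 (1.35), thymidine kinase Tk1 (1.81) and cyclin Ccna2 (1.84). Of 16 origin licensing and helicase genes 11 rose (16 adjusted over the list alone; median 1.02), among them Mcm10 (1.33), Dbf4 (1.51), Orc1 (1.21) and Orc6 (0.99). Of 4 GINS genes 3 rose (4 adjusted over the list alone; median 0.77). Of 31 Myc and ribosome biogenesis genes 6 rose (17 adjusted over the list alone; median 0.51), including Tfrc (1.05), Nolc1 (0.82), Fbl (0.80) and Wdr12 (0.76). These 5 lists passed camera with a preset correlation at adjusted p = 1.2e-30, 6.1e-17, 4e-11, 8.6e-04 and 4e-08 in the order given. None held with an estimated correlation (adjusted p = 0.31, 0.31, 0.33, 0.31 and 0.43). Without the block these were adjusted p = 0.053, 0.053, 0.074, 0.063 and 0.087 with an estimated correlation. With the block this correlation is estimated from 2 residual degrees of freedom, which leaves the test little power. No list passed it then in any contrast, and the lowest camera adjusted p was 0.22. A failure of this test with the block, here and below, therefore does not decide whether a list shifted.

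The LLC lists that moved down included hypoxia and glycolysis, with 7 of 20 genes lower (9 adjusted over the list alone; median −0.48). Among them were Ndrg1 (−1.45), Ero1a (−1.21), the glucose transporter Slc2a1 (−0.88) and the angiogenic factor Vegfa (−0.87). The interferon and antigen presentation list had 7 of 19 lower (9 adjusted over the list alone; median −0.65), including the class II genes H2-Aa (−1.64) and Cd74 (−1.30) with Oasl2 (−1.29) and Usp18 (−0.89). The immediate early list had 6 of 17 lower (10 adjusted over the list alone; median −0.52). Among them were Egr1 (−1.69), Zfp36 (−1.31), Btg2 (−1.23) and Fosb (−0.91). Btg2 was also the 1 of 11 p53 target genes that fell (1 adjusted over the list alone; list median −0.28). The mesenchymal list had 7 of 17 lower (7 adjusted over the list alone; median −0.34), with fibronectin Fn1 (−2.81), Mmp2 (−2.04), Tgfbi (−1.97) and Mmp14 (−1.38). Camera gave adjusted p = 1.5e-06 (hypoxia), 4.7e-08 (interferon), 1.3e-07 (immediate early), 0.015 (p53) and 1.6e-06 (mesenchymal). With an estimated correlation the adjusted p was 0.33 for p53 and 0.31 for the other 4. The p53 call ended without the LLC pair numbered 1 (median −0.16, adjusted p = 0.11). Fibroblast and macrophage markers were lower in the same arrays, with medians of −1.51 and −1.12.

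The colon26 comparison asked the same of the colon carcinoma. Mitosis and replication genes rose here too, and 14 of 17 macrophage markers and 4 of 12 endothelial markers fell. Fabp4, a fatty acid binding protein of adipocytes and macrophages, went from 9.83 ± 0.08 to 4.71 ± 0.08 (SD, n = 2 each), and Lyz2 from 10.83 ± 0.43 to 6.19 ± 0.42 (SD, n = 2 each). Aurkb went from 7.04 ± 0.46 to 9.27 ± 0.47 (SD, n = 2 each). The limma adjusted p-values were 2.2e-06 for Fabp4, 1.1e-06 for Lyz2 and 0.0024 for Aurkb. In all, 266 genes rose and 193 fell, of which 191 and 164 by more than 2-fold. The rises largest in size were those of Depdc1a (2.50), Spag5 (2.27), Aurkb (2.23), Esco2 (2.07), Gas2l3 (2.04), Aspm (2.01), Kif2c and Kif11 (1.95 each), Ube2c (1.94) and Nuf2 (1.93). The falls largest in size were those of Fabp5 (−5.20), Fabp4 (−5.12), Lyz1 (−5.11), Lyz2 (−4.64), Selenop (−4.60), Ctsc (−4.51), Ctss (−4.46), Ccl6 (−4.18), Cd163 (−4.14) and Col5a2 (−4.06). The falls of Fabp5, Fabp4, Ctsc and Cd163 ended at means under 5 and are limited in the same way. Lyz1 and Lyz2 are close in sequence, so their probe sets can each read both. Without the block limma called 3 genes, Fabp4, Lyz2 and the Fc receptor gene Fcgr3 (−3.34), all lower, with 438 at an unadjusted p under 0.05 against 609 from chance. Without the colon26 pair numbered 2, 0 genes rose and 59 fell in limma with the block, a fit in which the LLC pairs alone supply the spread. Without the pair numbered 1, 116 rose and 70 fell. The G2 and mitosis median was 1.11 in pair 1 and 2.18 in pair 2, and the S phase median 0.54 and 1.10. The median change of all genes was 0.08 as deposited, −0.01 after quantile normalization (43 rose, 109 fell) and 0.17 after median centring (539 rose, 232 fell).

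In the colon26 gene lists, 29 of 30 G2 and mitosis genes rose (30 adjusted over the list alone; median 1.62), including Ndc80 (1.64), Kif11, Aurkb and Ube2c. Of 29 S phase genes 15 rose (25 adjusted over the list alone; median 0.84). Among them were Rfc5 (1.11) of the clamp loader, Tk1 (1.33), the ribonucleotide reductase subunit Rrm1 (1.11) and the polymerase alpha subunit Pola1 (1.42). Of 16 licensing genes 4 rose (16 adjusted over the list alone; median 0.80): Dbf4 (1.40), Mcm10 (1.08), Gmnn (1.07) and Mcm3 (0.97). Of 4 GINS genes Gins1 rose (4 adjusted over the list alone; median 0.59). Of 31 Myc and ribosome biogenesis genes 0 passed limma's adjustment over all genes or over the list alone (median 0.37), with Npm1 at 0.12 and Odc1 at 0.00. Camera gave adjusted p = 9.9e-33, 1.7e-15, 2.2e-10, 0.0038 and 1.5e-04 in the order given. With an estimated correlation it gave adjusted p = 0.44, 0.44, 0.48, 0.44 and 0.63. Without the block the mitosis and S phase lists passed with an estimated correlation (adjusted p = 0.044 each), and the other 3 did not (0.097, 0.090 and 0.24). Of 20 hypoxia genes Adm fell (−1.47; list median −0.02). Camera's adjusted p of 0.019 for this list was an adjusted p = 0.44 with an estimated correlation. The median turned to 0.03 without the colon26 pair numbered 1 (adjusted p = 0.054). Of the immediate early genes Hspa1a fell (−1.72; list median 0.03, mean −0.08, camera adjusted p = 0.25), and of the mesenchymal genes Mmp2 fell (−0.77; list median 0.00, camera adjusted p = 0.21). The interferon list (median 0.09, with B2m at −0.01 and H2-D1 at 0.09) and the p53 list (median 0.10, with Cdkn1a at 0.10 and Ccng1 at 0.15) had 0 genes called in limma and a camera adjusted p of 0.73 each.

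Over both lines, asking what the lines had in common, EGFP-high cells had higher expression of replication and mitosis genes and lower expression of most macrophage, fibroblast and endothelial markers tested. Aurkb rose by 2.28 (SE 0.21, limma adjusted p = 1e-04), higher in 4 of 4 pairs, and Lyz2 fell by 3.40 (SE 0.13, limma adjusted p = 6.9e-07), lower in 4 of 4 pairs. In all 910 genes rose and 678 fell, of which 218 and 185 by more than 2-fold. After quantile normalization 703 rose and 595 fell, and after median centring 1184 and 626. The rises largest in size were those of Depdc1a (2.37), Aurkb (2.28), Spag5 (2.27), Depdc1b (2.14), Ube2c (2.10), Aurka and Gas2l3 (2.09 each), Nusap1 (2.08), Kif11 (2.06) and Prc1 (2.02). The falls largest in size were those of Ctsc (−3.65), Lyz1 (−3.64), Selenop (−3.61), Ctss and Fabp4 (−3.51 each), Lyz2 (−3.40), Postn (−3.37), Col5a2 (−3.17), Ccl8 (−3.09) and Ccl6 (−3.03), of which Ctsc, Fabp4 and Postn had a mean under 5 in the high cells of at least 1 line. All 30 mitosis genes, 26 of 29 S phase genes, 16 of 16 licensing genes and 4 of 4 GINS genes rose (30, 29, 16 and 4 adjusted over the list alone). Their medians were 1.78, 0.94, 0.86 and 0.68, with camera adjusted p of 1.9e-33, 1.5e-19, 9.5e-13 and 3.6e-04. With an estimated correlation the camera adjusted p was 0.27, 0.27, 0.31 and 0.27 with the block. Without the block it was 0.030, 0.030, 0.059 and 0.052, so the mitosis and S phase lists passed this version of camera only there. Fry with the block gave adjusted p = 0.044, 0.044, 0.073 and 0.044 over both lines. Fry gave 0.073, 0.073, 0.1 and 0.073 in LLC, and 0.14, 0.14, 0.2 and 0.14 in colon26. Lists that moved down were hypoxia (7 of 20 fell, 9 adjusted over the list alone; median −0.25), interferon (4 of 19, 4; −0.25), immediate early (5 of 17, 6; −0.25) and mesenchymal (6 of 17, 7; −0.17). Camera gave adjusted p = 7e-06, 8e-05, 8.1e-06 and 9.5e-05, and adjusted p = 0.26, 0.28, 0.27 and 0.27 with an estimated correlation. Fry gave adjusted p = 0.031 (hypoxia), 0.11 (interferon), 0.044 (immediate early) and 0.031 (mesenchymal). The medians of these lists were −0.48, −0.65, −0.52 and −0.34 in LLC but −0.02, 0.09, 0.03 and 0.00 in colon26. Their falls as a mean of the lines therefore lay mostly in LLC and were not common to both. The p53 list did not pass (median −0.05, adjusted p = 0.19). Without the block limma called 7 genes, all lower: Lyz1, Ctss, Fabp4, Lyz2, Fcgr3 (−2.50), S100a8 (−1.89) and Ctsk (−1.86), with 982 at an unadjusted p under 0.05 against 609 from chance. With the block, 1029 and 773 genes were called without the LLC pairs numbered 1 and 2, and 509 without the colon26 pair numbered 2.

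The calls of the lines overlapped: 217 genes rose in both, against 13.3 from chance (odds ratio 130, Fisher's exact p = 1.98e-248, two-sided). A further 74 fell in both, against 11.6 from chance (odds ratio 10.6, Fisher's exact p = 8.22e-41, two-sided). The tests of a gene in the 2 lines share 1 spread, and genes move together. The calls are therefore not independent, as the chance counts and Fisher's test take them to be, and these p-values are too small. No gene rose in one line and fell in the other, a count of 0 among the paired limma calls. Of the genes that rose in LLC, 93.4% had a positive change in colon26, and of those that fell in LLC, 66.7% had a negative one. Across all 12177 genes, which are not independent, the changes of the lines correlated at Pearson r = 0.48 and Spearman rho = 0.32. Without the colon26 pair numbered 2, 0 genes rose in both lines and 40 fell in both; without the colon26 pair numbered 1, 104 and 34 did. After quantile normalization 37 rose and 42 fell in both.

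**Figure D3:**
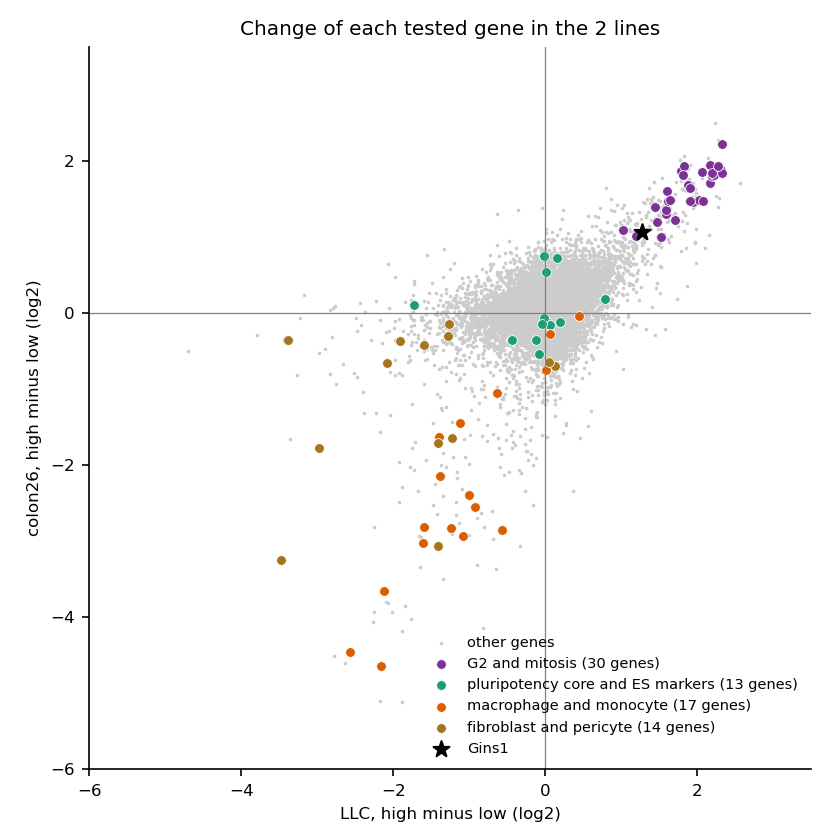
Log2 change, EGFP-high minus EGFP-low, of each tested gene in LLC (horizontal) and colon26 (vertical), with 4 gene lists in colour and Gins1 as a black star. Mitosis genes lie at positive values in both lines (medians 1.89 in LLC and 1.62 in colon26) and macrophage markers mostly at negative ones (−1.12 and −2.55).

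The series asked whether cells with high PSF1 activity resemble embryonic stem cells in expression. Of 30 genes in the pluripotency list 29 were named on the array and 13 were above the signal filter. Pou5f1 (Oct4), a core pluripotency factor, reached at most 4.43 on any array. Its group means were 3.71 in low and 3.99 in high cells of LLC and 4.04 and 4.31 in colon26. Nanog reached at most 4.01. Sox2 was at 3.10 and 3.09 in LLC. In colon26 it was at 9.65 in low and 10.41 in high cells, a change of 0.75 that did not pass (limma adjusted p = 0.054). Klf4 fell in LLC, from 7.31 ± 0.33 to 5.59 ± 0.35 (SD, n = 2 each; −1.72, limma adjusted p = 5.2e-04), and was at 11.31 and 11.42 in colon26. The difference between the lines was −1.83 (limma adjusted p = 0.013). Fibroblast and macrophage markers were lower in the same LLC arrays (medians −1.51 and −1.12). Whether the Klf4 fall lay in the tumour cells was not tested. Dnmt3l rose in LLC (0.79, limma adjusted p = 0.022), a call that ended without either LLC pair (0.99, adjusted p = 0.092, without number 1 and 0.59, 0.69, without number 2). Klf2 was at −0.44 in LLC and −0.36 in colon26, and Rif1 at 0.73 in colon26 (limma adjusted p = 0.086). The list's median change was −0.01 in LLC (1 rose, 1 fell; 1 and 1 adjusted over the list alone), −0.12 in colon26 (0 and 0 in limma over all genes; 2 and 0 adjusted over the list alone; mean 0.03) and −0.05 over both (1 and 1; 3 and 2 adjusted over the list alone). Camera gave adjusted p = 0.61, 0.69 and 0.63. The sign of these medians was not stable. With a filter of 7 the median was 0.32 in colon26 (adjusted p = 0.46) and 0.12 over both lines (0.64), and without the colon26 pair numbered 2 it was 0.11 (0.30) and 0.06 (0.74). The list's difference between lines had a median of 0.10 (camera adjusted p = 0.87), and −0.55 with a filter of 7, where it passed (0.024).

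Other programmes tied to embryonic or tumour stem cells were tested as lists. Ezh2, the methyltransferase of Polycomb repressive complex 2, rose by 1.12 in LLC and 1.08 in colon26 (limma adjusted p = 0.0049 and 0.012). Of 10 genes of that complex, 4 rose over both lines (5 rose and 1 fell adjusted over the list alone; median 0.32): Ezh2, Suz12 (0.53), Phf19 (0.59) and Eed (0.46), the last at an adjusted p of 0.050. The list gave camera adjusted p = 0.019 over both lines, 0.017 in colon26 (1 rose, 2 adjusted over the list alone; median 0.32) and 0.086 in LLC (Ezh2 rose, Ezh1 fell by 0.77; median 0.36). These became adjusted p = 0.62, 0.63 and 0.68 with an estimated correlation. Without the colon26 pair numbered 2 it was 0.057 over both lines (median 0.26) and 0.13 in colon26 (median 0.12). Ezh2 itself missed the call in LLC without the LLC pair numbered 2 (0.99, adjusted p = 0.15), and in colon26 without the colon26 pair numbered 1 (1.32, 0.063) or 2 (0.83, 0.32). Of 31 Myc and ribosome biogenesis genes 13 rose over both lines (19 adjusted over the list alone; median 0.38, camera adjusted p = 1.6e-08, adjusted p = 0.41 with an estimated correlation). Of 13 Polycomb-bound developmental regulators Pax6 rose over both lines (0.90, limma adjusted p = 0.0043; 1 rose and 1 fell adjusted over the list alone) and Pax3 fell in LLC (−0.74). The list medians were 0.02 in LLC, −0.04 in colon26 (mean 0.11) and 0.02 over both, at camera adjusted p = 0.59, 0.98 and 0.77. Without the colon26 pair numbered 2, Pax6 was at 0.68 over both lines (adjusted p = 0.061).

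Of 11 tumour stem cell surface and efflux markers tested, 4 fell over both lines: the efflux pump Abcb1a (−0.86), the surface proteins Thy1 (−1.49) and Alcam (−0.59), and the chemokine receptor Cxcr4 (−1.03). Adjusted over the list alone, 1 rose and 4 fell, and 3 of the 11 changes were positive. Alcam was at −1.12 in LLC but −0.05 in colon26, so its fall lay in LLC. Abcb1a was at −0.83 in LLC and −0.89 in colon26. Its LLC means were 4.72 in low and 3.89 in high cells, both under 5, where background limits a fall. Macrophage, fibroblast and endothelial markers were lower in the same arrays (medians −1.74, −1.41 and −0.68), and Thy1 and Cxcr4 are also made by cells other than tumour cells. The median change of this list was −0.24 in LLC (0 rose, 2 fell, the same adjusted over the list alone), −0.14 in colon26 (0 and 3, the same adjusted over the list alone) and −0.18 over both, at camera adjusted p = 0.048, 0.029 and 0.011. With an estimated correlation the adjusted p was 0.45, 0.58 and 0.39. The LLC call ended without the LLC pair numbered 1 (−0.41, adjusted p = 0.051) or 2 (−0.13, 0.12), the colon26 call without the colon26 pair numbered 1 (−0.04, 0.15). Among genes with a log2 signal above 7 the colon26 median was 0.08 (adjusted p = 0.26). Cd44 was at −0.22 in LLC and −0.14 in colon26 and did not pass.

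Among markers of other cell types that a dissociated tumour can hold, every gene called by limma in either line was lower in EGFP-high cells, with 0 higher. Of 17 macrophage and monocyte markers 10 fell in LLC and 14 in colon26 (1 rose and 14 fell, and 0 rose and 15 fell, adjusted over the list alone; medians −1.12 and −2.55). These included Ctss (−2.57 and −4.46), the mannose receptor Mrc1 (−2.12 and −3.66) and the CSF1 receptor Csf1r (−1.61 and −3.03). Of 14 fibroblast and pericyte markers 10 fell in LLC and 4 in colon26 (12 and 7 adjusted over the list alone; medians −1.51 and −0.66). Col1a1 fell by 2.08 and Pdgfrb by 1.91 in LLC, and Col6a3 by 3.07, Postn by 3.25, Lum by 1.77 and Fap by 1.65 in colon26. Of 12 endothelial markers 0 were called by limma in LLC (0 adjusted over the list alone; median −0.35) and 4 fell in colon26 (9 adjusted over the list alone; median −0.88): Plvap (−2.13), Emcn (−1.94), Cdh5 (−1.30) and Esam (−1.27). In LLC Plvap was at −0.54 and Eng at 0.02. The median signal of the endothelial markers there was 5.09 in low and 4.72 in high cells, where background limits a fall. Of 5 neutrophil markers S100a8 and S100a9 fell in LLC (−1.73 and −1.13; 2 adjusted over the list alone; list median −0.25), and these (−2.06 and −0.88) with Il1b (−1.81) and Mmp8 (−1.33) in colon26 (4 adjusted over the list alone; median −1.33). Camera gave adjusted p = 3.6e-10, 1.9e-12, 0.044 and 0.015 in LLC for macrophage, fibroblast, endothelial and neutrophil lists, and 3.2e-34, 4.1e-11, 9.9e-13 and 9.5e-08 in colon26. With an estimated correlation the adjusted p was 0.31, 0.31, 0.31 and 0.33 in LLC and 0.22, 0.37, 0.22 and 0.34 in colon26. Without the block it was 0.063, 0.053, 0.18 and 0.081 in LLC, and all 4 lists passed in colon26 (0.022, 0.045, 0.022 and 0.022). The LLC endothelial call ended without the LLC pair numbered 2 (−0.30, adjusted p = 0.23), and the colon26 call of Plvap without the colon26 pair numbered 2 (−1.77, 0.077).

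Over both lines 14 of 17 macrophage, 12 of 14 fibroblast, 7 of 12 endothelial and 4 of 5 neutrophil markers fell (15, 12, 9 and 4 adjusted over the list alone), with medians of −1.74, −1.41, −0.68 and −1.01. Camera gave adjusted p = 2.9e-21, 1e-15, 2e-07 and 2e-05 and, with an estimated correlation, adjusted p = 0.26, 0.26, 0.26 and 0.27. Without the block all 4 lists passed with an estimated correlation, at adjusted p = 0.030 each. Fry with the block gave adjusted p = 0.027, 0.044, 0.031 and 0.031 over both lines. Fry gave 0.047, 0.062, 0.1 and 0.062 in LLC, and 0.03, 0.14, 0.03 and 0.03 in colon26. Kdr, the VEGF receptor of endothelial cells, was among those that fell (−0.62). T and NK cell, B cell and skeletal muscle markers, with 3 genes tested in each list, had medians of 0.01, 0.08 and −0.04 over both lines and 0 calls in limma (camera adjusted p = 0.91, 0.91 and 0.74). Cd8a was at −0.08, Cd3e at 0.01, Ighm at 0.08, Pax5 at −0.14, Acta1 at −0.04 and Ckm at 0.01. Of the keratinocyte list 2 genes were tested, Krt10 (0.29) and Krt5 (0.15), and neither passed. Fabp4 was the 1 adipocyte gene tested, and 0 erythroid genes were above the filter.

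**Figure D4:**
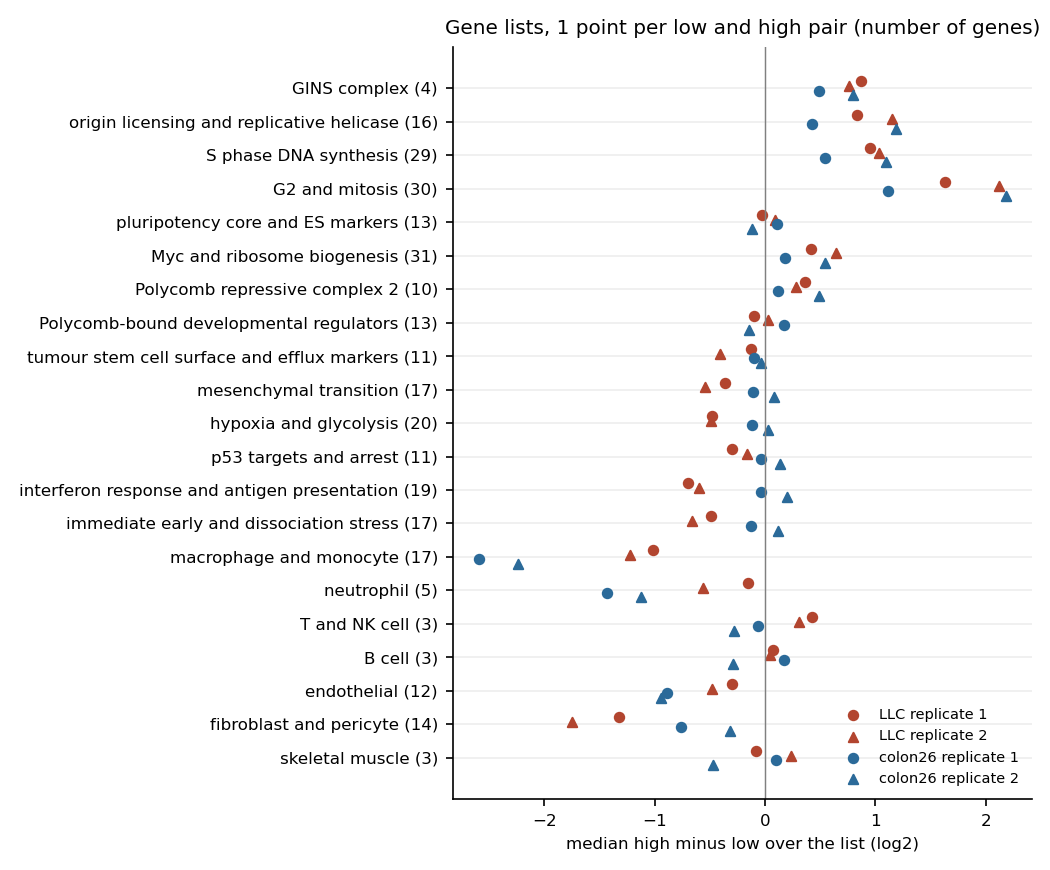
Median log2 change, EGFP-high minus EGFP-low, of 21 gene lists in each of the 4 pairs of arrays. The G2 and mitosis list lies at 1.63 and 2.12 in the LLC pairs and 1.11 and 2.18 in the colon26 pairs, the pluripotency list between −0.12 and 0.11, and the macrophage list between −2.59 and −1.01.

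The lines also differed in what changed, as tested by the LLC change minus the colon26 change. All LLC tumours grew for 4 weeks and all colon26 tumours for 2 weeks. Line and weeks of growth therefore cannot be told apart in this difference. Of the macrophage markers 7 fell further in colon26, and of the fibroblast markers 4 fell further in LLC and 1 in colon26. The differences with the most positive values were those of Fabp5 (5.93, at 0.73 in LLC and −5.20 in colon26), the scavenger receptor Cd163 (3.32), Fabp4 (3.23), Lyz1 (2.94) and Prg4 (2.74). Those with the most negative values were those of Aspn (−4.20), the elastase Mmp12 (−3.50), Osr2 (−3.40), Bmf (−3.16) and Col1a2 (−3.06). Aspn, Mmp12 and Bmf had group means under 5 in both colon26 groups, Cd163 and Prg4 in both LLC groups, and Fabp5, Fabp4 and Osr2 in the high cells of at least 1 line. Background limits a fall there, so the size and rank of these differences are not exact. The limma adjusted p-values ran from 9.2e-05 for Fabp5 to 0.033 for Col1a2. In all 172 genes differed, 52 with the higher and 120 with the lower change in LLC. Among the lists, 7 macrophage genes differed with a list median of 1.40 and 4 fibroblast genes with the opposite sign and a list median of −1.05, while Col6a3 differed in the macrophage direction (1.66) (camera adjusted p = 4.8e-15 and 0.015; adjusted p = 0.43 and 0.61 with an estimated correlation). Without the block limma called 0 genes, with 270 at an unadjusted p under 0.05 against 609 from chance. The count with the block was 0 without either colon26 pair, 90 without the LLC pair numbered 2, and 4 after quantile normalization.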

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

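The test of whether other cell types' markers were lower in all 4 pairs was chosen after the result was seen, as were the leaving out of pairs and the comparison of differences between single arrays.

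The arrays numbered 1 and 2 differed alike in all 4 groups, by a median of 0.44 per gene between single arrays against 0.24 between high and low. An unequal intensity distribution is argued against, since quantile normalization left 103.6% of the median absolute difference between the numbers. An unequal 3′ to 5′ representation of the labelled RNA may account for it: the 3′ minus 5′ index changed by −2.37 ± 0.27 (SD, n = 4 groups) from the arrays numbered 1 to those numbered 2, with 1 sign in all 4 groups. Actb and Gapdh carried most of this change. Tfrc moved less, from between 2.43 and 2.69 to between 1.37 and 2.16, and Pcx lay between −0.42 and 0.15 on all arrays. Across genes, the deviations from the group means correlated at Pearson r = 0.74 to 0.84 between LLC and colon26 arrays of the same number. Tumours of different lines are separate, so these values argue against single tumours as the source of the part that the lines share. A difference between tumours within a line, or between mice or handling common to a number, stays open, as untested. Without the block, 4 of the 35 splits of the 8 arrays into 4 and 4 called at least the 7 genes of the real one, so chance cannot be excluded for that count; the split by number called 4695 genes and that by line 3503, which points to a structure of the samples. With the block, 1588 genes were called by the real split, which was 1 of 8 that part all 4 pairs, too few for a share under 0.05. Another of these splits called 172 genes, but it swaps high and low in 1 line and so tests the difference between lines. The remaining ones called 0 genes, but they turn round single pairs within a line, which adds the real change to the spread. These splits therefore give no level to expect from chance.

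Of the macrophage, fibroblast, neutrophil and endothelial markers, 14 of 17, 12 of 14, 4 of 5 and 7 of 12 fell over both lines, though 0 of 12 endothelial markers were called by limma in LLC alone. The endothelial median signal in LLC low cells was 5.09, close to the filter of 5, so a fall could hardly be seen there. In high cells the median signal was 7.06 (LLC) and 8.76 (colon26) for fibroblast markers. It was 5.62 and 5.34 for macrophage, 5.16 and 5.39 for neutrophil, and 4.72 and 5.16 for endothelial markers. A shift of all genes at the same signal is argued against: genes matched on mean expression had a median change of 0.023 against −1.11 for the 48 markers, which is −2.1% of it. More host cells among the low cells, where the EGFP gate would leave cells without the transgene, may account for it, but cannot be told apart from lower expression in the tumour cells: 68.8% of the markers (33 of 48) were lower in all 4 pairs, against 9.2% of all genes, with 82.4% for macrophage, 85.7% for fibroblast, 60% for neutrophil and 33.3% for endothelial markers. What keeps this open is that lower expression in the tumour cells would give the same share, and that any depletion of host cells before the sort is not given in the sources used here.

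Replication and mitosis genes were higher in EGFP-high cells of both lines. Dilution of tumour transcripts by host cells in the low arrays is argued against as the whole cause, since it would raise every tumour-restricted gene as much. The 50 genes restricted to LLC had a median change of −0.21 (95% bootstrap interval −0.42 to −0.02) against 0.99 for S phase and 1.89 for mitosis genes. The 113 genes restricted to colon26 had a median change of 0.10 (0.03 to 0.17) against 0.84 and 1.62. The bootstrap resampled genes, which are not independent, so the intervals do not cover the spread between pairs. Restricted means a mean signal above 8 in the line and under 5.5 on every array of the other. This cut does not keep out genes of host cells, which would lower these medians. A hypothesis that EGFP-high cells hold more cycling tumour cells would fit these values, but no measure of the cell cycle other than expression was used here.

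The high minus low change differed between the lines in 172 genes by the blocked limma test, a count that fell to 0 without either colon26 pair. The lines also differed in weeks of growth, which cannot be told apart from line here. Each value that follows is the LLC change minus the colon26 change in log2, singled out because that difference passed the adjusted p. Among myeloid genes it was 2.48 for Lyz2, 2.94 for Lyz1, 1.89 for Ctss, 1.42 for Csf1r, 1.69 for Fcgr3, 3.32 for Cd163, 2.30 for Ccl6, 1.68 for Ccl8, 2.02 for Clec4n, 1.21 for Mmp8, −3.50 for Mmp12 and −2.03 for Arg1. Among matrix, fibroblast and mesenchymal genes it was −4.20 for Aspn, −3.03 for Dcn, −3.06 for Col1a2, −1.42 for Col1a1, 1.66 for Col6a3, −1.53 for Pdgfrb, −2.49 for Fn1, −2.43 for Vcan, −1.87 for Tgfbi, −1.28 for Mmp2, −2.43 for Mmp3 and 2.74 for Prg4. For endothelial Plvap and Emcn it was 1.59 and 1.71, and for the stress and immediate early genes Egr1, Fosb and Hspa1a −1.77, −1.40 and 1.45. For the remaining genes it was 5.93 for Fabp5, 3.23 for Fabp4, 1.97 for Selenop, −3.16 for Bmf, −2.44 for C1s1, −2.85 for Ddr1, −3.40 for Osr2 and −1.83 for Klf4. Background limits the sizes for genes with a group mean under 5 in both groups of a line (Cd163, Prg4, Mmp8 and Emcn in LLC; Mmp12, Arg1, Aspn, Bmf and C1s1 in colon26) or in the high cells alone (Fcgr3, Clec4n, Fabp4, Fabp5, Osr2, Mmp2 and Hspa1a), so these are not exact.

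Among the gene lists, camera on the difference between lines passed for S phase (median 0.15), mitosis (0.27), Myc (0.18), mesenchymal (−0.45), hypoxia (−0.48), p53 (−0.37), interferon (−0.62), immediate early (−0.64), macrophage (1.40), neutrophil (0.33), endothelial (0.58) and fibroblast (−1.05) genes. With an estimated correlation none of these 12 passed, at adjusted p from 0.43 to 0.71. Without the colon26 pair numbered 1, the S phase and mitosis medians were −0.12 and −0.18.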

How the results depend on the processing

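The filters, arrays of a line, scalings, moderation and probe set choices combined with the block, the block shared by the lines and the leaving out of pairs were chosen after the data were seen; the block itself, the estimated correlation and fry were set before. Where a cause is not named, the cause was not tested. Without the block, adding it took the genes called to 1342 (LLC), 459 (colon26), 1588 (both lines) and 172 (difference between lines), and the shared calls to 291; taking it away gives 0, 3, 7, 0 and 0. Without the block the colon26 count was 0 with only the arrays of the line, with array weights and with every probe set, and 5 with trend and robust moderation; the count over both lines was 0 with every probe set. Leaving out 1 array, which leaves a group with a lone array assumed to vary like the others, gave 0 to 18 genes in colon26 and 0 to 41 over both lines, the highest without colon26 low replicate 2.

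With the block, the difference between lines gave 56 genes with no filter, 272 with a filter of 7, 4 after quantile normalization, 374 after median centring and 320 with trend and robust moderation. The shared calls were 193 with no filter and 79 after quantile normalization, and the colon26 count was 152 after quantile normalization and 771 after median centring. With every probe set as a unit, 2419 were called in LLC and 2384 over both lines, from 25626 units. With a block shared by the lines, the counts were 802, 204, 1052 and 12, with 137 shared. Leaving out 1 pair, which leaves the spread to the pairs of the other line, gave 396 to 943 genes in LLC, 59 to 552 in colon26, 509 to 1109 over both lines, 0 to 175 for the difference between lines, and 40 to 253 shared calls. Named genes with the block kept their side of the threshold in 2341 comparisons with an alternative, lost the call in 595 (224 of these without the block, 80 without colon26 pair 2, 60 without pair 1, 45 after quantile normalization) and gained it in 3. A turn of sign where neither setting passed was counted among the 2341.

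List medians that turned sign included the following, with and without the block unless said. With a filter of 7, which leaves fewer genes, the stem cell marker list in colon26 was at 0.08. The pluripotency list was then at 0.32 in colon26 and 0.12 over both lines, neither past the threshold. Its difference between lines went from 0.10 to −0.55 and passed (camera adjusted p = 0.030 without the block and 0.024 with it). The pluripotency median in colon26 was also 0.12 without colon26 low replicate 2 and 0.02 without colon26 high replicate 1, and 0.11 without colon26 pair 2; in LLC, where it was −0.01, it lay between −0.03 and 0.09. The hypoxia list in colon26 was at 0.06 after median centring and 0.01 with the mean of probe sets; leaving out arrays gave −0.27 to 0.08, and leaving out pairs −0.12 to 0.03. Without the block, leaving out arrays gave −0.02 to 0.75 for the Polycomb repressive complex 2 list in colon26, −0.19 to 0.68 for the mitosis and −1.16 to 0.06 for the immediate early difference between lines. With it, leaving out pairs gave −0.12 to 0.47 for the S phase and −0.18 to 0.78 for the mitosis difference. The counts that follow leave out the pluripotency list's changes in LLC, in colon26 and over both lines. Of list results with the block, 1000 comparisons kept their side of the threshold, 131 lost the call, 8 gained it and 7 reversed. Of the calls lost, 54 were lost with an estimated correlation and 38 with fry. A turn of sign where neither setting passed was counted among the 1000. Background limits how far a signal near or under the filter of 5 can fall, as for Emcn and Mmp8 in LLC and for Aspn, Mmp12, Bmf, C1s1 and Arg1 in colon26.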

Other observations

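The gene families, their members, the sex-linked genes and the probe set comparisons in this part were chosen after their values were seen. Families were taken as the 140 groups of at least 10 tested genes whose symbols share 3 or more letters before the first digit, and the genes called over both lines with the block were counted in each by one-sided Fisher's exact tests (280 tests, Benjamini-Hochberg adjusted). Genes of nuclear pore proteins rose, 11 of 18 Nup genes (adjusted p = 1e-06), with Nup37 at 1.10, Nup43 at 1.04 and Nup107 at 0.83. Genes of DNA repair by recombination and related steps rose, 9 of 14 Rad genes (adjusted p = 7e-06), with Rad51ap1 at 1.52, Rad54b at 1.32 and Rad18 at 1.31. The Mcm helicase genes (8 of 10, adjusted p = 3.5e-06), the kinesins Kif (10 of 27, 5.4e-04), the centrosomal Cep genes (10 of 35, 0.0053, with Cep55 at 1.83), the Lsm genes of RNA processing (5 of 12, 0.033, with Lsm2 at 0.94) and the Cdc genes (8 of 31, 0.037) also rose. The symbols group genes by name, and Cdc, Cep and Rad each hold genes of several functions. Fisher's exact test takes genes as independent, which genes that move together are not, and no family was tested with an estimated correlation. With one, the mitosis and licensing lists, which share genes with Kif and Mcm, had camera adjusted p = 0.27 and 0.31 with the block. Without the block these were 0.030 and 0.059.

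Collagen genes fell, 14 of 28 (adjusted p = 1.3e-08; 1 rose), as did 8 of 14 matrix metalloproteinase genes (1.1e-05), with Mmp3 at −1.75 and Mmp13 at −1.23, and 4 of 10 Adamts genes (0.037). Of the chemokines, 7 of 15 Ccl genes (3.3e-04), with Ccl12 at −2.53 and Ccl9 at −1.76, and 4 of 11 Cxcl genes (0.046), with Cxcl12 at −1.92, fell, and so did 6 of 13 C-type lectin genes (0.0012), with Clec4n at −1.81. Of 11 Parp genes 4 fell and 2 rose (0.046 for the falls), with Parp14 at −0.61 and Parp1, the main poly-ADP-ribose polymerase of DNA damage, at 0.61. After quantile normalization the counts were 8 Nup, 6 Rad, 7 Mcm, 10 Kif, 7 Cep, 3 Lsm and 7 Cdc genes that rose, and 10 collagen, 8 Mmp, 4 Adamts, 7 Ccl, 3 Cxcl, 3 Clec and 3 Parp genes that fell. After median centring they were 11, 9, 8, 10, 11, 5 and 9, and 13, 9, 5, 7, 4, 6 and 3. Fibroblast and macrophage markers were lower in the same arrays, with medians of −1.41 and −1.74 and 12 of 14 and 14 of 17 called. Without the block limma called 0 genes of these 14 families; over all genes tested, 982 were at an unadjusted p under 0.05.

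Xist, the RNA of the inactive X chromosome, was at 7.14 and 6.18 in LLC low and 5.56 and 5.40 in LLC high, and at 10.09 and 7.39 in colon26 low and 6.85 and 5.66 in colon26 high, lower in the high array of 4 of 4 pairs (limma adjusted p = 0.0033 over both lines, with the block and no filter). The Y-linked Eif2s3y was at 8.0 and 7.88 in LLC low and 7.81 and 7.32 in LLC high, and between 3.33 and 3.72 on the colon26 arrays. Of 151 named genes, 13 had probe sets above the filter that changed in opposite directions over both lines, among them Ddr1 (−1.36 to 0.13), Ezh1 (−0.34 to 0.03) and Vegfa (−0.43 to 0.13). For other genes a further probe set stayed near 0 over both lines, so their values rest on part of their probe sets: Bmf (−1.65 to −0.11), Csf1r (−2.32 to −0.12), Col1a2 (−2.08 to −0.18), Pax6 (0.02 to 0.90), Phf19 (0.00 to 0.59), Wdr12 (0.07 to 0.63) and Pax3 (−0.34 to 0.00).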
